A study of Arabidopsis thaliana with 6 samples.

How the data were processed

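Messenger RNA was measured by sequencing in 6 libraries of *cat2-2* leaves, 3 sampled at high CO2 and 3 after 3 h of high light in ambient air. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy kits and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.3.3, aligned to the TAIR10 genome with TopHat2 2.1.0 and assigned to genes with featureCounts of Subread 1.4.6. Their parameters, including the strand setting and the treatment of reads that match several places, are not given in the sources used here. The deposited values are raw counts of reads per gene, not normalized, in 1 table with a column per library. Of its 33604 rows, 2 were leftover header lines and were left out, which left 33602 genes, 23860 of them with at least 1 count. All 133 chloroplast and 146 mitochondrial genes are listed at 0 in the deposited counts, so no organelle share or organelle gene test was possible, and leaving these genes out changes nothing.

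Groups were taken from the sample titles. Library totals ranged from 18047295 to 24149149 counts. A count of 0 over the 3 libraries of a group allows up to 3 counts, and folds against such a group are given as lower bounds against that floor. For genes with 1 to 3 counts in a group the ratio is given with a 95% exact binomial interval of the counts. Replicate libraries differed by far more than counting noise (chi-square per degree of freedom 9.65 to 52.4), and no library was a copy of another. The labels call the replicates biological repeats.

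Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: genes were kept by filterByExpr at its default minimum of 10 counts (18504 genes, holding 99.9% of counts), libraries were scaled by TMM factors (0.932 to 1.06), and a quasi-likelihood model with robust dispersions (glmQLFit, glmQLFTest) compared high light with high CO2 with 4 residual degrees of freedom. The biological coefficient of variation was 0.177. P-values are two-sided and adjusted by Benjamini-Hochberg, and a gene is called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes. The standard error of a log2 fold change is its unshrunken size divided by the square root of the F statistic, and no standard error is given for genes at 0 counts in a group.

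Before the data were examined, 32 gene lists with 520 memberships (516 loci) were fixed by locus, from photosynthesis and photorespiration to stress, hormones, the clock and markers of other cell types and organs. HSP17.6A as AT1G59860 and CNX2 as AT5G07340 were then dropped, because the annotation did not pair locus and symbol, which left 518 memberships (514 loci). Lists with at least 3 tested members, 31 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera called 22 lists, 12 of them higher and 10 lower in high light. With an estimated correlation it called 0 (smallest adjusted p = 0.11), while fry, which asks only whether members move one way on balance, called 29. Counts of risen and fallen members adjusted over the list alone equalled those over all genes for 28 of 32 lists. The others were endoplasmic reticulum folding stress (13 risen), abscisic acid and dehydration (15 risen, 1 fallen), ribosome biogenesis (5 risen) and vascular markers (1 risen, 6 fallen). The named genes follow a rule also fixed then: the 3 catalases; the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between groups; 3 called members of each main list, 2 of them the largest changes in the direction most called members take and 1 the largest in the other direction where there is one; up to 2 of each further list in the same order; and every called member of the cell type and organ lists.

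Gene names and exons came from the TAIR10.1 annotation, which matched 32835 of the 33602 loci. Its build name differs from that of the counts, so no coordinates are given. Coding sequences of the 530 listed or named loci were compared with all others by BLAST 2.17.0. Of these, 14 had a copy of at least 95% identity over at least 50% of their length, RBCS1B and RBCS2B among the 101 named genes and LHCB1.1, LHCB1.2, LHCB1.3, LHCB2.1, LHCB2.2, KIN1, KIN2, BIP1, BIP2, PGLP1, RVE7 and DHAR1 among the other list members. Their values are uncertain where the counting split or dropped shared reads. Of the named genes, 4 shared more than 10% of their exon bases with a gene on the opposite strand (KNOLLE, DTX1, LHCB2.3 and CESA8) and 0 with a gene on the same strand. Some other list members shared more with the opposite strand, such as MYC2 (98.5%), DREB2B (69.5%) and GSTF2 (60.5%), and their values are uncertain where the counting ignored strand. F3H of the flavonoid list shared 93.8% in this way, had 1 count in all and could not be tested. Reads lost in the counting cannot be told apart there from an absent transcript.

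The fit was tested on simulated counts drawn for 18504 genes from the mean, dispersion and library size of the real data, with 200 genes changed. Of the simulated genes 18364 passed the filter. The fit called 16% of genes changed by 1.5-fold, 62% at 2-fold, 94% at 4-fold and 98% at 16-fold, and 14 of 18168 unchanged genes. In the real data 60.8% of tested genes were called, a far larger part than the 200 changed here. These shares may therefore not carry over to the data. A simulated set of 20 risen genes, picked from the smallest change of 1.5-fold upward, had a camera adjusted p of 1.1e-19. With an estimated correlation its camera adjusted p was 0.059. Of 20 unchanged sets 0 were called. Simulated genes were drawn independently, while estimated correlations in the data reached 0.893 (light-harvesting antenna). The unchanged sets therefore do not test the preset correlation for the real lists. The alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library totals only), no filter or a stricter one, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, an adjusted p under 0.01 and a test against a log2 fold change of 1.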

Results

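The series asked how leaves of the *Arabidopsis thaliana* mutant *cat2-2* changed their transcripts under photorespiratory stress. CAT2 is the main leaf catalase, a peroxisomal enzyme that breaks down the hydrogen peroxide made in photorespiration. Plants of the Columbia-0 background were grown for 3 weeks at 3000 ppm CO2, which holds photorespiration low, under 120 µmol m-2 s-1 light, 75% relative humidity and a day of 16 h light and 8 h dark. One group of 3 libraries was sampled there at 0 h (high CO2). The other group of 3 libraries was sampled after 3 h in ambient air of 400 ppm CO2 under 1200 µmol m-2 s-1 light and 55% relative humidity in another growth chamber (high light). Each library was made from middle-aged leaves of 15 pooled plants, and the whole set-up was repeated for the 3 biological repeats. CO2, light, humidity, chamber and sampling time changed together, and no wild type was among the samples, so a difference between the groups belongs to the whole change of conditions.

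Strand-specific mRNA sequencing gave 22130229, 24149149 and 18047295 counts in the high CO2 libraries and 21967471, 21672913 and 21685292 in the high light libraries, over 33602 genes. A count of 0 over a group allows up to 3 counts, which equal 0.0477 CPM (read counts normalised to library size) in high CO2 and 0.0451 CPM in high light. Intervals and floors cover counting error only. In high CO2 a larger part of all counts came from few genes: the 10 most counted genes of a library held 11.5% ± 1.12 (SD, n = 3) of its counts there and 5.72% ± 0.639 (n = 3) in high light. The exact permutation test gave p = 0.1 (two-sided), the smallest that 3 against 3 libraries can give. RBCS1A (AT1G67090), a small subunit of Rubisco, was the most counted gene in every library. Errors given below are SD over 3 libraries for CPM and the standard error of the fit for log2 fold changes, which are high light against high CO2. Called genes have an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

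The mutated gene was looked at first. CAT2 (AT4G35090) transcripts were still counted in every library, with 1760, 2427 and 1752 counts in high CO2 and 724, 1010 and 928 in high light, and they fell from 94.1 ± 12.6 to 40.0 ± 5.65 CPM (log2 fold change -1.24 ± 0.16, edgeR adjusted p = 1.9e-04). The other catalase genes rose: CAT3 (AT1G20620) from 2217 ± 259 to 3359.6 ± 218 CPM (log2 fold change 0.60 ± 0.15, edgeR adjusted p = 0.00909) and CAT1 (AT1G20630) from 65.3 ± 5.96 to 90.0 ± 4.60 CPM (log2 fold change 0.46 ± 0.12, edgeR adjusted p = 0.0105). CAT3 was the most abundant catalase transcript in both groups. Without a wild type, these levels do not show how far the mutation lowered CAT2. With upper-quartile scaling the rises of CAT1 and CAT3 were not called (log2 fold changes 0.19 and 0.33, edgeR adjusted p = 0.17 and 0.082, in ranges of 0.00772 to 0.172 and 0.00414 to 0.0823 over their edgeR refits, with DESeq2 adjusted p = 0.00104 and 8.3e-05 and limma-voom adjusted p = 0.00919 and 0.00754).

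**Figure D1:**
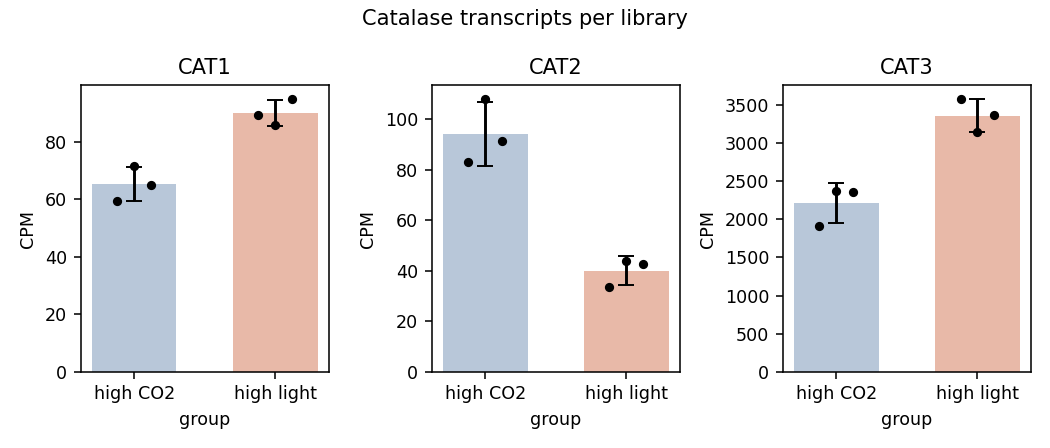
Normalised abundance (CPM, axes from 0) of CAT1, CAT2 and CAT3 in the 3 high CO2 and the 3 high light libraries; bars are group means, error bars SD and dots single libraries. CAT2 fell from 94.1 ± 12.6 to 40.0 ± 5.65 CPM, while CAT1 and CAT3 lay higher in all 3 high light libraries than in any high CO2 library.

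The comparison of high light with high CO2 asked which leaf transcripts follow the shift to photorespiratory conditions. Of 18504 genes tested, 5631 rose and 5616 fell, of which 3528 and 2514 by at least 2-fold. The 3 libraries of each group lay apart, without overlap, for 67.2% of tested genes, against 10% by chance. Among called genes with a mean log2 CPM of at least 2 and no overlap between the groups' libraries, the largest rises by fitted log2 fold change reached transcripts that were barely or never counted in high CO2. At 0 counts the data bound this value only from below, so the rank of such genes is uncertain. With limma-voom it was 10.56, 9.535 and 8.353 for DTX1, AT3G44830 and AT2G23270, below the 12.07 of HSP17.4. DTX1 (AT2G04040), a MATE efflux family protein, had 0 counts over the high CO2 group and 37.5 ± 11.6 CPM in high light, at least 784-fold higher against the floor over the group (edgeR adjusted p = 7.9e-06). AT3G44830, of the lecithin:cholesterol acyltransferase family, and AT2G23270, of unknown function, also had 0 counts in high CO2 and were at least 402-fold and 177-fold higher (edgeR adjusted p = 5.5e-05 and 8.8e-05). Without replicate 3 of both groups the 3 bounds were 478, 196 and 109-fold. Without high CO2 replicate 1 they were 520.4, 267 and 118-fold and without high CO2 replicate 2 504, 258 and 114-fold, as the floor rises 1.51 and 1.56 times with fewer counts. In all, 52 of the risen genes had 0 counts in high CO2. The small heat shock genes HSP17.4 (AT3G46230) and HSP17.6A (AT5G12030) rose from 0.227 ± 0.308 to 544 ± 107 CPM and from 0.345 ± 0.472 to 585 ± 102 CPM, and the DnaJ-domain gene AT1G71000 from 0.137 ± 0.120 to 220.1 ± 6.73 CPM (edgeR adjusted p = 1.3e-06, 1.9e-06 and 2.5e-07). The protein phosphatase 2C gene AT1G07160 had 3 counts in high CO2, all in replicate 2, and rose 1839-fold by counts, with a 95% counting interval of 629 to 8920.0 (edgeR adjusted p = 2.7e-07). The ratio was 1219.9-fold (interval 417 to 5917) without high CO2 replicate 1, at least 1181-fold without high CO2 replicate 2 and 1221-fold (interval 418 to 5925) without replicate 3 of both groups. The F-box gene AT5G55150 had 1 count there, in replicate 1, and rose 2764-fold by counts, with a 95% counting interval of 496 to 109215 (edgeR adjusted p = 1.8e-05). Its high light libraries held 712, 483 and 1729 counts, and the ratio was at least 611-fold without high CO2 replicate 1, 1775-fold (interval 318 to 70130.4) without high CO2 replicate 2, 1679-fold (interval 301 to 66389) without high light replicate 3 and 1166-fold (interval 209 to 46107) without replicate 3 of both groups.

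Within the same limits the largest falls were smaller than the largest rises. GA3OX1 (AT1G15550), which makes active gibberellin, had the largest fall within these limits, from 8.37 ± 2.16 to 0.444 ± 0.389 CPM (log2 fold change -4.20 ± 0.52, edgeR adjusted p = 1.5e-04). Leaving out high light replicate 2 moved its log2 fold change to -5.01 and that of SAUR20 from -3.36 to -3.94. The clock gene LHY (AT1G01060) fell from 60.6 ± 9.03 to 5.22 ± 1.65 CPM, the wall polysaccharide gene CSLA01 (AT4G16590) from 145 ± 17.7 to 13.7 ± 7.08 CPM, the lipid transfer gene LTP6 (AT3G08770) from 21.1 ± 7.52 to 2.01 ± 0.918 CPM and the auxin-induced gene SAUR20 (AT5G18020) from 8.93 ± 2.51 to 0.861 ± 0.519 CPM (edgeR adjusted p = 3.7e-06, 7.4e-05, 9.2e-05 and 1.1e-04). TRM24 (AT5G51850), AT5G62210 and the leucine-rich repeat gene AT3G17640 completed the 8 largest falls within these limits, with log2 fold changes of -3.79 ± 0.31, -3.78 ± 0.24 and -3.45 ± 0.17 (edgeR adjusted p = 1.5e-05, 3.5e-06 and 8.5e-07). Among the 6 libraries, replicate 3 of both groups stood apart on the second principal component, which held 4.90% of the variance against 89.6% on the first. Without replicate 3 of both groups, an alternative chosen after seeing the data, 5807 genes rose and 4869 fell. Upper-quartile scaling moved the median log2 fold change of all tested genes from -0.06 to -0.33 and the calls to 4386 risen and 7883 fallen, so 35.7% of calls were rises against 50.1%.

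**Figure D2:**
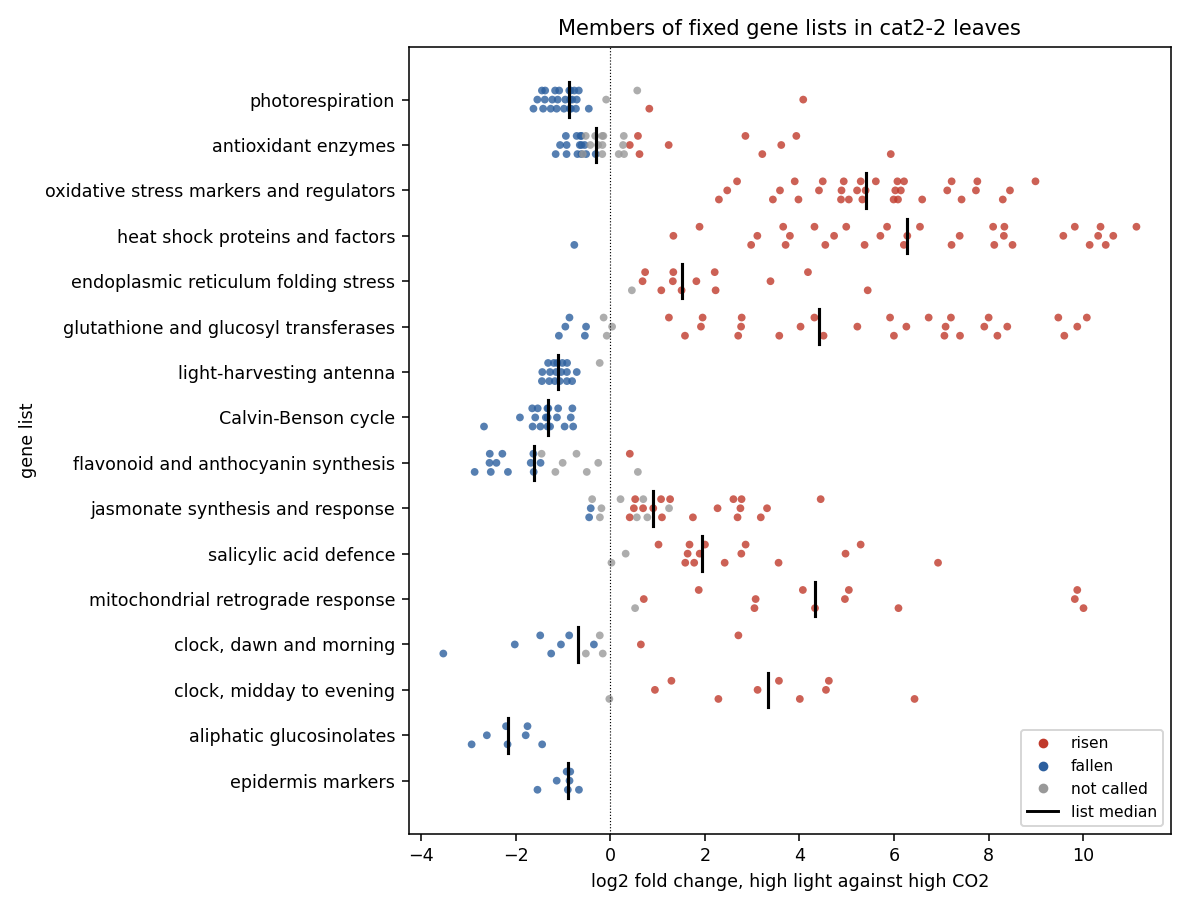
Log2 fold change of each tested member of 16 gene lists (dots; red risen, blue fallen, grey not called; vertical position within a list carries no value) with the list median as a black line. The heat shock list spans -0.76 to 11.13, while 17 of 18 antenna and 19 of 19 Calvin-Benson cycle members fell. Members at 0 counts in high CO2, 1 of the heat shock and 2 of the transferase list, are drawn unmarked at their fitted value, though their folds are only bounded from below.

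Gene lists fixed before the data were examined were then counted. Counts of risen and fallen members adjusted over the list alone were the same as those given here for 28 of 32 lists. All 33 tested members of the list of oxidative stress markers and regulators rose, with a median log2 fold change of 5.40 (camera adjusted p = 5.9e-49; adjusted p = 0.108 with an estimated correlation). The transcription factor gene DREB2A (AT5G05410) rose from 0.897 ± 0.127 to 284 ± 70.5 CPM and the zinc-finger gene ZAT11 (AT2G37430) from 0.0662 ± 0.0576 to 24.4 ± 7.62 CPM (edgeR adjusted p = 2.2e-07 and 2.0e-06). WRKY75 (AT5G13080), with 3 counts in high CO2, rose 569-fold by counts, with a 95% counting interval of 194 to 2762 (edgeR adjusted p = 1.1e-06). Of these 3 counts 2 were in replicate 2, and the ratio was 1096-fold (interval 197 to 43325) without high CO2 replicate 2 and 321-fold (interval 109.7 to 1561) without replicate 3 of both groups. Of 13 mitochondrial retrograde response genes, known to rise when mitochondria are disturbed, 12 rose and 1 was not called, with a median of 4.33 (camera adjusted p = 9.8e-11; adjusted p = 0.203 with an estimated correlation). Its members UPOX, UGT74E2 and HSP23.5 also belong to the oxidative stress, transferase and heat shock lists, in that order, so these lists are not separate evidence. AOX1D (AT1G32350), an alternative oxidase, rose from 0.362 ± 0.496 to 395 ± 184 CPM, UGT74E2 (AT1G05680), an auxin glucosyltransferase, from 1.73 ± 1.81 to 1667 ± 257 CPM and HSP23.5 (AT5G51440) from 1.37 ± 1.43 to 1276 ± 123 CPM (edgeR adjusted p = 6.7e-06, 6.7e-06 and 4.0e-06). High CO2 replicate 2 held most of the few counts these genes had in high CO2: UGT74E2 had 85 there against 22 and 7 in replicates 1 and 3. Without that library the log2 fold changes of AOX1D, UGT74E2 and HSP23.5 were 12.29, 11.22 and 11.21, against 10.01, 9.88 and 9.83 with it. AOX1D had 10.77 with limma-voom and 9.23 without replicate 3 of both groups.

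Heat shock transcripts had the largest median rise of the 32 lists. Of 33 tested heat shock proteins and factors 32 rose, with a median of 6.28 (camera adjusted p = 4.6e-34, or adjusted p = 0.165 with an estimated correlation). The labels give 21 °C for both groups, and leaf temperature was not given in the sources used here. Among members with a count in high CO2, HSP17.4 and HSP17.6A rose most, with log2 fold changes of 11.13 ± 0.60 and 10.64 ± 0.61. These were 13.29 and 12.87 without high CO2 replicate 2 and 12.07 and 11.43 with limma-voom. The list held 1 member at 0 counts in high CO2, whose fold is only bounded from below. The plastid chaperone CLPB3 (AT5G15450) was the exception and fell from 387 ± 109.8 to 228 ± 47.8 CPM (log2 fold change -0.76 ± 0.24, edgeR adjusted p = 0.0209). CLPB3 was not called without high CO2 replicate 2, without high CO2 replicate 3, without high light replicate 1 and without replicate 3 of both groups. For CLPB3 the log2 fold changes there were -0.80, -0.46, -0.60 and -0.48 (edgeR adjusted p = 0.0511, 0.0775, 0.0704 and 0.0938, in a range of 0.00244 to 0.0938 over its edgeR refits; DESeq2 adjusted p = 0.00750, limma-voom adjusted p = 0.0205). Of 13 genes of endoplasmic reticulum folding stress 12 rose, with a median of 1.51 (camera adjusted p = 2.5e-05; adjusted p = 0.438 with an estimated correlation). ERDJ3A (AT3G08970) rose from 2.81 ± 0.787 to 123 ± 25.2 CPM, the transcription factor gene BZIP60 (AT1G42990) from 23.8 ± 3.83 to 431 ± 79.7 CPM and the chaperone gene BIP3 (AT1G09080) from 2.32 ± 1.12 to 24.3 ± 9.96 CPM (edgeR adjusted p = 7.7e-07, 1.0e-06 and 1.4e-04). BIP1 and BIP2, in the same list, have near-identical coding sequences, so the counting could move reads between them.

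Glutathione transferases and stress-related glycosyltransferases, which conjugate reactive and foreign compounds, rose for 28 of 36 tested members and fell for 5. Their median was 4.41, or 4.18 with the members at 0 counts in high CO2 set to their lower bound (camera adjusted p = 1.7e-18; adjusted p = 0.203 with an estimated correlation). GSTU22 (AT1G78340), with 2 counts in high CO2, both in replicate 1, rose 1271-fold by counts, with a 95% counting interval of 352 to 10504 (edgeR adjusted p = 1.3e-06). Its ratio was at least 562-fold without high CO2 replicate 1, 816-fold (interval 226 to 6745) without high CO2 replicate 2 and 708-fold (interval 196 to 5853) without replicate 3 of both groups. The transferase list had 25 to 28 risen and 1 to 5 fallen members over 13 refits (median 4.13 to 4.58). Transferase members risen and fallen numbered 28 and 3 without high CO2 replicate 1 or without high light replicate 2 or without replicate 3 of both groups, 28 and 1 without high CO2 replicate 2 and 28 and 2 without high light replicate 3. GSTU26 (AT1G17190) fell from 4.03 ± 0.137 to 1.90 ± 0.930 CPM (log2 fold change -1.09 ± 0.32, edgeR adjusted p = 0.0169). GSTU26 was not called without high CO2 replicate 2, without high light replicate 3 and without replicate 3 of both groups. For GSTU26 the log2 fold changes there were -1.03, -1.02 and -0.97 (edgeR adjusted p = 0.0534, 0.0520 and 0.0637, in a range of 0.00243 to 0.0637 over its edgeR refits; DESeq2 adjusted p = 0.00919, limma-voom adjusted p = 0.00907). Sulfur assimilation and glutathione synthesis genes rose for 8 of 15 members and fell for 2, with a median of 0.54 (camera adjusted p = 0.00690; adjusted p = 0.203 with an estimated correlation). The sulfur list had 7 to 9 risen and 1 to 3 fallen members over 13 refits (median 0.27 to 0.79). Sulfur members risen and fallen numbered 8 and 1 with DESeq2 size factors or with library totals only or with no filter or without high CO2 replicate 1 or without high CO2 replicate 2 or without high CO2 replicate 3 or without high light replicate 1 or without high light replicate 2 or without high light replicate 3 and 9 and 1 without replicate 3 of both groups. The serine acetyltransferase gene SERAT2-1 (AT1G55920) rose from 48.0 ± 4.03 to 760.4 ± 42.4 CPM and the APS reductase gene APR3 (AT4G21990) from 148 ± 11.2 to 2048 ± 303 CPM (edgeR adjusted p = 3.1e-07 and 7.1e-07).

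The antioxidant enzymes went both ways. Of 37 tested members 9 rose and 15 fell, with a median of -0.31, a mean of 0.26 and no call for the list (camera adjusted p = 0.846; adjusted p = 0.934 with an estimated correlation). The antioxidant list had 6 to 10 risen and 8 to 24 fallen members over 13 refits (median -0.58 to -0.24). Antioxidant members risen and fallen numbered 6 and 24 with upper-quartile factors and 8 and 8 without high CO2 replicate 2. Without high CO2 replicate 1 10 fell. The cytosolic ascorbate peroxidase gene APX2 (AT3G09640), with 1 count in high CO2, in replicate 2, rose 83.2-fold by counts, with a 95% counting interval of 14.5 to 3323 (edgeR adjusted p = 1.2e-04), and without that library 0 counts remained in high CO2. Its ratio was 55.2-fold (interval 9.65 to 2204) without high CO2 replicate 1. The plastid peroxiredoxin PRXIIE (AT3G52960) fell from 222 ± 54.8 to 99.3 ± 21.1 CPM and the organellar glutathione reductase GR2 (AT3G54660) from 362 ± 6.72 to 173 ± 19.2 CPM (edgeR adjusted p = 0.00217 and 2.2e-04). Peroxisome biogenesis genes also went both ways, with 10 of 22 risen and 6 fallen and no call for the list (camera adjusted p = 0.699; adjusted p = 0.855 with an estimated correlation). The peroxisome list had 7 to 11 risen and 5 to 9 fallen members over 13 refits (median 0.04 to 0.43). With upper-quartile factors 7 rose and 9 fell. The peroxisome list was called upward by fry, which tests against no change (fry adjusted p = 0.016). The peroxins PEX3B (AT1G48635) and PEX19A (AT3G03490) rose most in that list, with log2 fold changes of 1.62 ± 0.13 and 1.32 ± 0.13 (edgeR adjusted p = 1.5e-05 and 3.5e-05).

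Photorespiratory and photosynthetic transcripts mostly fell. Of 29 photorespiration genes 25 fell and 2 rose, with a median of -0.87 (camera adjusted p = 3.2e-05; adjusted p = 0.252 with an estimated correlation). The glycine decarboxylase genes GLDP2 (AT2G26080) and GLDP1 (AT4G33010) fell from 962 ± 157 to 311 ± 29.9 CPM and from 3633 ± 633 to 1244 ± 147 CPM (edgeR adjusted p = 6.1e-05 and 1.2e-04). The glycolate oxidase gene GOX3 (AT4G18360) rose from 0.336 ± 0.0917 to 5.76 ± 4.45 CPM (log2 fold change 4.08 ± 0.62, edgeR adjusted p = 5.4e-04), and its log2 fold change was 3.23 without high light replicate 3 and 3.48 without replicate 3 of both groups. PGLP1 (AT5G36700) has a copy with an identical coding sequence, AT5G36790, so its 87 counts are uncertain. All 19 Calvin-Benson cycle genes fell, with a median of -1.33 (camera adjusted p = 1.4e-06; adjusted p = 0.468 with an estimated correlation). The aldolase gene FBA1 (AT2G21330) fell from 3202 ± 542 to 849.5 ± 172 CPM (edgeR adjusted p = 8.5e-05). RBCS1B (AT5G38430) and RBCS2B (AT5G38420), which share 97.2% of coding bases so that reads may have moved between them, had log2 fold changes of -2.67 ± 0.38 and -1.65 ± 0.22 (edgeR adjusted p = 3.8e-04 and 2.5e-04).

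Of 18 light-harvesting antenna genes 17 fell and 1 was not called, with a median of -1.10 (camera adjusted p = 1.2e-04; adjusted p = 0.517 with an estimated correlation). LHCB4.3 (AT2G40100) fell from 712 ± 55.8 to 262 ± 40.3 CPM and LHCB6 (AT1G15820) from 6181 ± 1492 to 2479 ± 503 CPM (edgeR adjusted p = 9.7e-05 and 0.00124). LHCB2.3 (AT3G27690) fell from 2158 ± 387 to 790.4 ± 64.8 CPM (edgeR adjusted p = 1.6e-04); 40.6% of its exon bases are shared with a gene on the opposite strand, and the strand setting of the counting was not given in the sources used here. Photoprotection genes fell for 12 of 19 members and rose for 5 (camera adjusted p = 0.0287; adjusted p = 0.372 with an estimated correlation), and without high light replicate 2 the list was not called (camera adjusted p = 0.0594, in a range of 0.0130 to 0.0594 over its camera refits with the preset correlation). Fry, which tests against no change, called this list (adjusted p = 0.00224). The photoprotection list had 3 to 5 risen and 11 to 14 fallen members over 13 refits (median -1.08 to -0.70). Photoprotection members risen and fallen numbered 3 and 13 with upper-quartile factors. The early light-induced gene ELIP2 (AT4G14690) fell from 40.1 ± 1.55 to 13.2 ± 5.79 CPM and the ascorbate synthesis gene VTC2 (AT4G26850) from 776 ± 62.2 to 258 ± 20.3 CPM (edgeR adjusted p = 0.00106 and 2.6e-05). Epidermis markers moved with these groups: all 7 fell, with a median of -0.90 (camera adjusted p = 0.0183; adjusted p = 0.468 with an estimated correlation).

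Secondary metabolism split by pathway. Flavonoid and anthocyanin synthesis genes fell for 11 of 19 tested members and rose for 1, with a median of -1.62 (camera adjusted p = 0.00355; adjusted p = 0.548 with an estimated correlation). The flavonoid list had 0 to 1 risen and 7 to 15 fallen members over 13 refits (median -2.12 to -1.20). Flavonoid members risen and fallen numbered 0 and 14 with upper-quartile factors, 0 and 12 without high CO2 replicate 1 or without high light replicate 2, 0 and 10 without high CO2 replicate 2, 1 and 7 without high CO2 replicate 3, 0 and 15 without high light replicate 3 and 0 and 8 without replicate 3 of both groups. HY5 was the member that rose. The regulator MYB111 (AT5G49330) and flavonol synthase FLS1 (AT5G08640) fell, with log2 fold changes of -2.87 ± 0.33 and -2.56 ± 0.20 (edgeR adjusted p = 1.1e-04 and 1.2e-05). HY5 (AT5G11260), a light-signalling transcription factor gene, rose from 6.81 ± 0.359 to 9.06 ± 0.844 CPM (log2 fold change 0.41 ± 0.14, edgeR adjusted p = 0.0333). HY5 was not called with upper-quartile factors, without high CO2 replicate 1, without high CO2 replicate 2, without high light replicate 2, without high light replicate 3 and without replicate 3 of both groups. For HY5 the log2 fold changes there were 0.14, 0.46, 0.46, 0.37, 0.38 and 0.41 (edgeR adjusted p = 0.398, 0.0552, 0.0717, 0.0930, 0.0955 and 0.0785, in a range of 0.0215 to 0.398 over its edgeR refits; DESeq2 adjusted p = 0.0353, limma-voom adjusted p = 0.0356). All 7 aliphatic glucosinolate genes fell, with a median of -2.18 (camera adjusted p = 1.3e-07; adjusted p = 0.165 with an estimated correlation). Their regulators MYB29 (AT5G07690) and MYB28 (AT5G61420) fell from 56.3 ± 1.57 to 7.35 ± 0.920 CPM and from 139 ± 3.93 to 22.6 ± 1.67 CPM (edgeR adjusted p = 6.7e-07 and 7.2e-07). Camalexin and indole glucosinolate genes rose for 7 of 11 tested members and fell for 2, with a median of 4.49 (camera adjusted p = 0.0118; adjusted p = 0.382 with an estimated correlation), and the list was not called without high CO2 replicate 3 or without replicate 3 of both groups (camera adjusted p = 0.0576 and 0.0502, in a range of 1.4e-04 to 0.0576 over its camera refits with the preset correlation). Fry, which tests against no change, called this list (adjusted p = 0.00130). The camalexin list had 7 risen and 2 to 3 fallen members over 13 refits (median 2.73 to 4.64). PAD3 (AT3G26830), the last enzyme of camalexin synthesis, rose from 5.12 ± 5.12 to 1560.3 ± 460.4 CPM (edgeR adjusted p = 2.9e-05), with a log2 fold change of 8.24 ± 0.74, or 9.52 without high CO2 replicate 2. MYB122 (AT1G74080) had 0 counts in high CO2 and was at least 79.3-fold higher (edgeR adjusted p = 4.2e-04), with 52, 56 and 142 counts in the high light libraries. Its bound was 50.6-fold without high light replicate 3, 35.1-fold without replicate 3 of both groups, and 52.6 and 50.9-fold without high CO2 replicates 1 and 2.

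Hormone-related defence genes mostly rose. Salicylic acid defence genes rose for 14 of 16 members and fell for 0, with a median of 1.95 (camera adjusted p = 2.2e-07; adjusted p = 0.372 with an estimated correlation). The glutaredoxin GRX480 (AT1G28480) rose from 0.388 ± 0.242 to 49.1 ± 14.6 CPM, ALD1 (AT2G13810) from 0.471 ± 0.219 to 18.9 ± 1.06 CPM and FMO1 (AT1G19250) from 0.191 ± 0.0430 to 6.18 ± 2.28 CPM (edgeR adjusted p = 1.3e-06, 7.6e-07 and 1.9e-05). The log2 fold change of GRX480 was 6.93, and 7.62 without high CO2 replicate 2. Jasmonate synthesis and response genes rose for 17 of 27 tested members and fell for 2, with a median of 0.91 (camera adjusted p = 0.00784; adjusted p = 0.548 with an estimated correlation). The jasmonate list had 11 to 21 risen and 0 to 4 fallen members over 13 refits (median 0.54 to 1.16 over 12 of them, and above that without replicate 3 of both groups). Jasmonate members risen and fallen numbered 17 and 0 with DESeq2 size factors or with library totals only or without replicate 3 of both groups, 11 and 4 with upper-quartile factors, 14 and 1 with no filter, 12 and 1 without high CO2 replicate 1, 11 and 0 without high CO2 replicate 2, 16 and 0 without high CO2 replicate 3, 12 and 4 without high light replicate 1, 14 and 0 without high light replicate 2 and 21 and 0 without high light replicate 3. AOC3 (AT3G25780), of jasmonate synthesis, rose from 2.46 ± 0.444 to 53.8 ± 14.3 CPM and the repressor gene JAZ1 (AT1G19180) from 12.1 ± 0.995 to 120.5 ± 11.1 CPM (edgeR adjusted p = 1.7e-06 and 4.2e-07). LOX2 (AT3G45140) fell from 3326 ± 408 to 2436 ± 313 CPM (log2 fold change -0.45 ± 0.17, edgeR adjusted p = 0.0434). LOX2 was not called with DESeq2 size factors, with library totals only, with no filter, without high CO2 replicate 2, without high CO2 replicate 3, without high light replicate 2, without high light replicate 3 and without replicate 3 of both groups. For LOX2 the log2 fold changes there were -0.41, -0.41, -0.45, -0.42, -0.30, -0.39, -0.40 and -0.24 (edgeR adjusted p = 0.0649, 0.0534, 0.0539, 0.133, 0.185, 0.139, 0.127 and 0.324, in a range of 0.00508 to 0.324 over its edgeR refits; DESeq2 adjusted p = 0.0342, limma-voom adjusted p = 0.0386). Abscisic acid and dehydration genes rose for 15 of 24 tested members and fell for 0 (camera adjusted p = 0.00946; adjusted p = 0.548 with an estimated correlation). The abscisic acid list had 13 to 17 risen and 0 to 3 fallen members over 13 refits (median 1.28 to 1.89). Abscisic acid members risen and fallen numbered 14 and 3 with upper-quartile factors or without high light replicate 1, 15 and 1 with no filter and 13 and 1 with the replicate block. The phosphatase HAI1 (AT5G59220) rose with a log2 fold change of 4.43 ± 0.28, and LEA7 (AT1G52690), with 3 counts in high CO2, 50.1-fold by counts, with a 95% counting interval of 16.8 to 246 (edgeR adjusted p = 3.5e-06 and 0.00318). The high light libraries held 119, 21 and 19 counts of LEA7, whose ratio was 33.2-fold (interval 11.2 to 163) without high CO2 replicate 1, 96.5-fold (interval 17.1 to 3836) without high CO2 replicate 2 and 18.7-fold (interval 5.95 to 94.4) without high light replicate 1.

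Growth-related transcripts fell in part. Auxin response genes fell for 10 of 14 tested members and rose for 3 (camera adjusted p = 0.0198; adjusted p = 0.517 with an estimated correlation), with IAA29 (AT4G32280) and IAA5 (AT1G15580) falling from 5.89 ± 2.53 to 0.213 ± 0.110 CPM and from 1.88 ± 1.04 to 0.361 ± 0.164 CPM (edgeR adjusted p = 7.0e-05 and 0.00341). Expansins and wall-loosening genes fell for 9 of 12 members and rose for 1 (camera adjusted p = 0.00765; adjusted p = 0.517 with an estimated correlation), with log2 fold changes of -2.50 ± 0.22 and -2.39 ± 0.25 for EXPA5 (AT3G29030) and EXPA15 (AT2G03090) (edgeR adjusted p = 2.2e-05 and 6.3e-05). Ribosome biogenesis genes rose for 6 of 12 members, without a call for the list (camera adjusted p = 0.252; adjusted p = 0.756 with an estimated correlation). The ribosome list had 3 to 9 risen and 0 to 1 fallen members over 13 refits (median 0.47 to 0.93). Ribosome members risen and fallen numbered 3 and 0 with upper-quartile factors, 8 and 1 without high CO2 replicate 3 and 7 and 1 without replicate 3 of both groups. RID2 (AT5G57280) and TOZ (AT5G16750) had log2 fold changes of 1.32 ± 0.24 and 1.16 ± 0.19 (edgeR adjusted p = 0.00140 and 7.7e-04). The 3 touch genes rose (camera adjusted p = 7.1e-04; adjusted p = 0.165 with an estimated correlation), TCH4 (AT5G57560) from 1.90 ± 0.814 to 81.4 ± 54.5 CPM and TCH3 (AT2G41100) from 50.7 ± 4.11 to 1154 ± 160.1 CPM (edgeR adjusted p = 9.1e-05 and 3.4e-07). Without high light replicate 2 the log2 fold change of TCH4 was 4.77 against 5.41.

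Senescence and chlorophyll breakdown genes rose for 5 of 7 tested members, without a call for the list (camera adjusted p = 0.167; adjusted p = 0.548 with an estimated correlation), and the list was called without high CO2 replicate 3 and without replicate 3 of both groups (camera adjusted p = 0.0478 and 0.0449, in a range of 0.0449 to 0.197 over its camera refits with the preset correlation). Fry, which tests against no change, called this list (adjusted p = 0.00646). SAG13 (AT2G29350) rose from 10.9 ± 8.75 to 477 ± 242 CPM and the transcription factor gene ORE1 (AT5G39610) from 2.55 ± 2.12 to 15.1 ± 3.51 CPM (edgeR adjusted p = 2.0e-04 and 0.00140). The log2 fold change of SAG13 was 5.44, and 6.30 without high CO2 replicate 2. That of ORE1 was 2.58, and 3.56 without high CO2 replicate 3 and 3.39 without replicate 3 of both groups. Low-sugar markers rose for 6 of 12 members and fell for 1, also without a call (camera adjusted p = 0.139; adjusted p = 0.548 with an estimated correlation), and were called without high light replicate 3 (camera adjusted p = 0.0446, in a range of 0.0446 to 0.252 over its camera refits with the preset correlation). Fry, which tests against no change, called this list (adjusted p = 0.0156). The low-sugar list had 5 to 8 risen and 1 to 2 fallen members over 13 refits (median 1.29 to 1.94). Low-sugar members risen and fallen numbered 5 and 2 with upper-quartile factors, 8 and 2 with the replicate block, 6 and 2 without high CO2 replicate 3 and 7 and 2 without replicate 3 of both groups. DRM2 (AT2G33830) and DIN2 (AT3G60140) rose from 0.897 ± 0.443 to 17.1 ± 5.35 CPM and from 0.805 ± 0.657 to 11.1 ± 5.22 CPM (edgeR adjusted p = 2.6e-05 and 3.1e-04). The log2 fold change of DIN2 was 3.77, and 4.70 without high CO2 replicate 1. That of DRM2 was 4.27, and 4.89 without replicate 3 of both groups, an alternative chosen after seeing the data.

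Clock transcripts shifted between the groups, which were sampled 3 h apart in their treatment. Of 10 clock genes that peak from midday to the evening 9 rose and 1 was not called, with a median of 3.34 (camera adjusted p = 9.9e-08; adjusted p = 0.203 with an estimated correlation). FKF1 (AT1G68050) rose from 0.332 ± 0.0607 to 29.4 ± 7.33 CPM and PRR3 (AT5G60100) from 0.569 ± 0.0846 to 14.2 ± 3.08 CPM (edgeR adjusted p = 4.6e-07 and 1.4e-06). Of 12 dawn and morning clock genes 7 fell and 2 rose, with a median of -0.70 (camera adjusted p = 0.00926; adjusted p = 0.372 with an estimated correlation). The dawn list had 1 to 2 risen and 6 to 10 fallen members over 13 refits (median -0.96 to -0.55). Dawn members risen and fallen numbered 1 and 10 with upper-quartile factors, 1 and 6 without high CO2 replicate 1 or without high CO2 replicate 3 or without replicate 3 of both groups and 1 and 7 without high light replicate 2 or without high light replicate 3. LHY and LNK4 (AT5G06980) fell by 3.54 and 2.02 on the log2 scale (edgeR adjusted p = 3.7e-06 and 2.1e-05). The time of day of each sampling was not given in the sources used here.

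**Figure D3:**
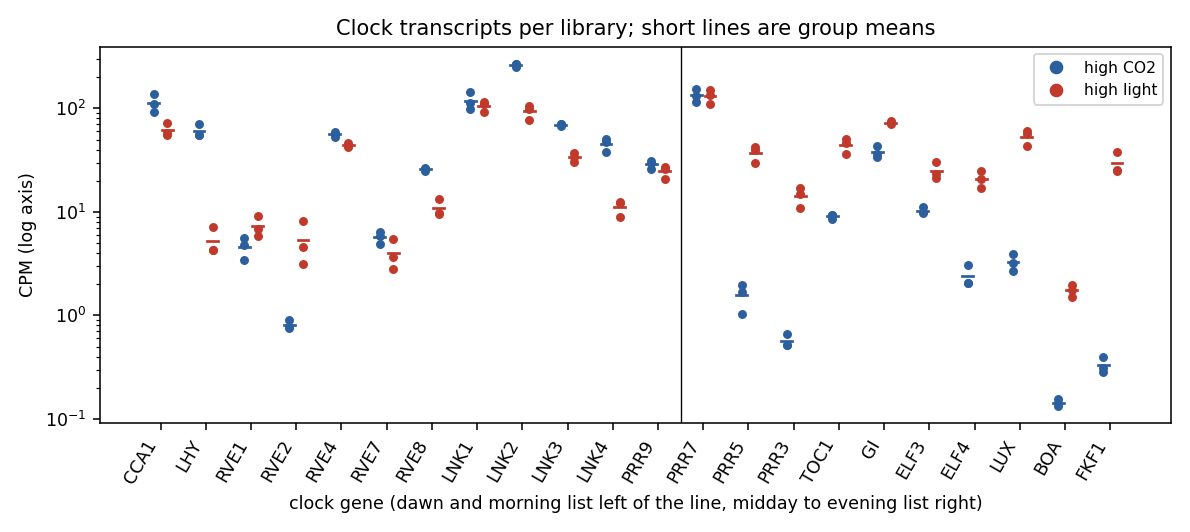
Abundance (CPM, log axis) of the 22 clock genes in the 6 libraries; dots are libraries (blue high CO2, red high light) and short lines group means. FKF1 went from 0.332 ± 0.0607 to 29.4 ± 7.33 CPM and LHY from 60.6 ± 9.03 to 5.22 ± 1.65 CPM.

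Markers of other cell types and organs were measured alongside. The flower list also holds FT and SOC1, which act in flowering time and do not mark flower tissue. Guard cell markers rose for 1 of 5 and fell for 2, vascular markers rose for 1 of 9 and fell for 5, and the dividing cell and flower lists fell for 4 of 4 and 2 of 3 tested members. Camera did not call these 4 lists (camera adjusted p = 0.292, 0.257, 0.190 and 0.430). All 4 were called downward by fry, which tests against no change (fry adjusted p = 0.0031, 0.029, 0.016 and 0.036). The vascular list had 1 risen and 2 to 8 fallen members over 13 refits (median -0.74 to -0.40). Vascular members risen and fallen numbered 1 and 8 with upper-quartile factors, 1 and 3 without high CO2 replicate 1 or without high light replicate 2 and 1 and 2 without high CO2 replicate 2. The dividing cell list had 0 risen and 2 to 4 fallen members over 13 refits (median -1.20 to -0.81). Dividing cell members risen and fallen numbered 0 and 2 with DESeq2 size factors or with library totals only or without high CO2 replicate 1 or without high CO2 replicate 2 or without high light replicate 1 or without high light replicate 2 or without high light replicate 3. The flower list had 0 risen and 0 to 2 fallen members over 13 refits (median -1.49 to -0.59). Flower members risen and fallen numbered 0 and 1 with the stricter filter and 0 and 0 without high CO2 replicate 2 or without high CO2 replicate 3 or without high light replicate 1 or without high light replicate 2. The guard cell list had 0 to 1 risen and 2 to 3 fallen members over 13 refits (median -0.62 to -0.23). Guard cell members risen and fallen numbered 0 and 3 with upper-quartile factors. The guard cell genes MYB60 (AT1G08810), FAMA (AT3G24140) and KAT1 (AT5G46240) had log2 fold changes of -1.48 ± 0.14, -0.82 ± 0.15 and 0.63 ± 0.18 (edgeR adjusted p = 3.1e-05, 0.00143 and 0.0135). Among vascular genes SWEET12 (AT5G23660) rose, with a log2 fold change of 1.13 ± 0.13, while CESA4 (AT5G44030) and CESA8 (AT4G18780) fell by 0.82 and 0.80 on the log2 scale (edgeR adjusted p = 1.1e-04, 0.00404 and 0.0125). SUC2 (AT1G22710), APL (AT1G79430) and XCP1 (AT4G35350) fell, with log2 fold changes of -0.50 ± 0.15, -0.47 ± 0.13 and -0.43 ± 0.14 (edgeR adjusted p = 0.0197, 0.0119 and 0.0248). SUC2 was not called without high CO2 replicate 2, without high light replicate 1 and without high light replicate 2. For SUC2 the log2 fold changes there were -0.44, -0.46 and -0.41 (edgeR adjusted p = 0.0878, 0.0639 and 0.0728, in a range of 0.00173 to 0.0878 over its edgeR refits; DESeq2 adjusted p = 0.0126, limma-voom adjusted p = 0.0148). APL was not called without high CO2 replicate 1 and without high CO2 replicate 2. For APL the log2 fold changes there were -0.39 and -0.40 (edgeR adjusted p = 0.0566 and 0.0685, in a range of 0.00116 to 0.0685 over its edgeR refits; DESeq2 adjusted p = 0.0180, limma-voom adjusted p = 0.0125). XCP1 was not called with the DESeq2 Wald test, without high CO2 replicate 1, without high CO2 replicate 2, without high light replicate 2 and without high light replicate 3. For XCP1 the log2 fold changes with edgeR there were -0.35, -0.36, -0.43 and -0.40 (edgeR adjusted p = 0.105, 0.120, 0.0632 and 0.0760, in a range of 0.00244 to 0.120 over its edgeR refits; DESeq2 adjusted p = 0.0566, limma-voom adjusted p = 0.0265). KAT1 was not called with upper-quartile factors. For KAT1 the log2 fold change there was 0.36 (edgeR adjusted p = 0.103, in a range of 0.00406 to 0.103 over its edgeR refits; DESeq2 adjusted p = 0.00305, limma-voom adjusted p = 0.0165).

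Among genes of the epidermis, dividing cell and flower lists, LTP1 (AT2G38540), CYCB1-1 (AT4G37490), KNOLLE (AT1G08560), AG (AT4G18960) and FT (AT1G65480) fell, with log2 fold changes of -0.67 ± 0.24, -0.75 ± 0.28, -0.58 ± 0.22, -1.22 ± 0.36 and -1.49 ± 0.47 (edgeR adjusted p = 0.0393, 0.0416, 0.0426, 0.0170 and 0.0221). LTP1 was not called without high CO2 replicate 1, without high CO2 replicate 2, without high light replicate 2 and without high light replicate 3. For LTP1 the log2 fold changes there were -0.53, -0.57, -0.58 and -0.51 (edgeR adjusted p = 0.117, 0.121, 0.127 and 0.128, in a range of 0.00323 to 0.128 over its edgeR refits; DESeq2 adjusted p = 0.0213, limma-voom adjusted p = 0.0321). CYCB1-1 was not called with DESeq2 size factors, with library totals only, with no filter, with the DESeq2 Wald test, with the replicate block, without high CO2 replicate 1, without high CO2 replicate 2, without high CO2 replicate 3, without high light replicate 1, without high light replicate 2, without high light replicate 3 and without replicate 3 of both groups. For CYCB1-1 the log2 fold changes with edgeR there were -0.71, -0.69, -0.75, -0.74, -0.62, -0.77, -0.73, -0.73, -0.83, -0.68 and -0.65 (edgeR adjusted p = 0.0512, 0.0665, 0.0720, 0.0653, 0.161, 0.0942, 0.0877, 0.0972, 0.0626, 0.115 and 0.167, in a range of 0.0108 to 0.167 over its edgeR refits; DESeq2 adjusted p = 0.185, limma-voom adjusted p = 0.0474). KNOLLE was not called with DESeq2 size factors, with library totals only, with the DESeq2 Wald test, without high CO2 replicate 1, without high CO2 replicate 2, without high light replicate 1, without high light replicate 2 and without high light replicate 3. For KNOLLE the log2 fold changes with edgeR there were -0.54, -0.52, -0.38, -0.54, -0.68, -0.60 and -0.48 (edgeR adjusted p = 0.0521, 0.0553, 0.185, 0.112, 0.0518, 0.0843 and 0.131, in a range of 0.00883 to 0.185 over its edgeR refits; DESeq2 adjusted p = 0.0720, limma-voom adjusted p = 0.0490). AG was not called without high CO2 replicate 2, without high CO2 replicate 3, without high light replicate 1 and without high light replicate 2. For AG the log2 fold changes there were -1.21, -0.92, -1.17 and -1.07 (edgeR adjusted p = 0.0521, 0.0705, 0.0539 and 0.0614, in a range of 0.00570 to 0.0705 over its edgeR refits; DESeq2 adjusted p = 0.0413, limma-voom adjusted p = 0.0224). FT was not called without high CO2 replicate 2, without high CO2 replicate 3, without high light replicate 1 and without high light replicate 2. For FT the log2 fold changes there were -1.43, -1.21, -1.25 and -1.16 (edgeR adjusted p = 0.0583, 0.0846, 0.0789 and 0.0705, in a range of 6.5e-04 to 0.0846 over its edgeR refits; DESeq2 adjusted p = 0.00488, limma-voom adjusted p = 0.0119). Without high light replicate 3 the log2 fold change of FT was -2.29. KNOLLE shares 33.5% of its exon bases with a gene on the opposite strand. The other epidermis markers ABCG12 (AT1G51500), ATML1 (AT4G21750), KCS6, CER1, FDH and PDF1 fell by 1.14, 0.85, 0.93, 0.86, 0.90 and 1.54 on the log2 scale (edgeR adjusted p = 9.1e-05, 4.6e-04, 0.00111, 0.00751, 3.3e-04 and 0.0132). CYCD3-1 and CDKB2-1 fell by 1.12 and 1.12 (edgeR adjusted p = 0.00182 and 0.00444). Of the root markers only NRT2.1 (AT1G08090) had enough counts to be tested, and its difference of -0.86 ± 0.41 was not called (edgeR adjusted p = 0.0971). Chloroplast and mitochondrial genes, 133 and 146 in number, were listed at 0 in every library.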

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

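Leaving out replicate 3 of both groups was chosen after the data were seen, as were the refits of clock members, the count ratios, lower bounds and list counts without libraries, and the stricter thresholds for named genes. Between 5058 and 6108 genes rose and 4274 and 5368 fell when single libraries were left out. Of the 11247 called genes, 9188 were still called without high CO2 replicate 2, the fewest of these refits, and 10422 without high CO2 replicate 3, the most. With upper-quartile factors 10002 were. In any refit that tested them, 0 of the 11247 changed direction. The refits reuse the same libraries, so a change of direction was unlikely from the start and the 0 says little. The counts that left the 1.5-fold range were 2599 risen and 1025 fallen when tested against a log2 fold change of 1, which asks for more by construction, and 4008 falls of at least 2-fold with upper-quartile factors, under which the median of all genes was -0.33. That scaling also ended the calls of CAT1 (0.46 to 0.19) and CAT3 (0.60 to 0.33). Both moved about as far as the median of all tested genes, which went from -0.06 to -0.33. Why this scaling differed from the others was not tested. With an estimated correlation 0 lists were called; the adjusted p were 0.252 (photorespiration), 0.108 (oxidative stress markers and regulators), 0.165 (heat shock proteins and factors), 0.438 (endoplasmic reticulum folding stress), 0.203 (glutathione and glucosyl transferases), 0.517 (light-harvesting antenna), 0.468 (Calvin-Benson cycle), 0.548 (flavonoid and anthocyanin synthesis), 0.548 (jasmonate synthesis and response), 0.372 (salicylic acid defence), 0.203 (mitochondrial retrograde response). In simulated counts a set of risen genes, picked from the smallest change of 1.5-fold upward, also missed that threshold (0.059). Its changes were far smaller than the medians of several lists, so it does not tell how the test treats those lists. The antioxidant enzymes were not called by camera in any setting, nor by directional fry, which was run on the main fit only. Their direction turned upward with fry (adjusted p = 0.240) and without high light replicate 2, and the cause of the turn was not tested. Camera adjusted p ran from 0.622 to 0.927 when single libraries were left out. Fry's mixed test, which asks whether members change in either direction, called this list (adjusted p = 6.6e-05). As 60.8% of all tested genes were called, that does not set the list apart. Other lists kept direction and side of the threshold in 240 of 246 refits with the preset correlation, and fry called 7 of them that camera did not. Of 1466 refits of the 98 named genes other than catalases, 1402 kept direction and call, 64 lost the call and 0 reversed. In each refit at an adjusted p under 0.05, 86 of 101 named genes kept the call. All 101 were called in the main fit and most were named for large changes, so these shares do not describe the 11247 calls. Stricter thresholds asked for more: 85 of 101 had an adjusted p under 0.01 and 68 passed the test against a log2 fold change of 1. No list median changed sign under any scaling.

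Replicate numbers were not used to pair libraries, since deviations from the group means correlated by 0.219, -0.0207 and 0.410 for numbers 1, 2 and 3, and not every library correlated best with its own number. With the replicate block 5880 genes rose and 6071 fell. Leaving out organelle genes gave no new value because they are all at 0. The share of counts in the 50 instead of the 10 most counted genes differed by -11.1 percentage points (exact permutation p = 0.1). Genes with few counts in high CO2 limit the precision of the largest folds.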

Other observations

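The tests of the clock pattern, of high CO2 replicate 2, of near-identical copies and of other splits of the libraries were chosen only after those results were seen. The matched-list and GC content tests were set down before their results, with the list medians already known. Gene families named by the annotation's product text, with at least 15 tested members, gave 106 further groups, of which camera called 17, and 0 with an estimated correlation. VQ motif proteins, partners of WRKY transcription factors, rose for 15 of 21 members and fell for 0 (camera adjusted p = 1.1e-07; adjusted p = 0.952 with an estimated correlation). Calcium-binding EF-hand proteins rose for 19 of 30 and fell for 4 (camera adjusted p = 2.5e-05; adjusted p = 0.952 with an estimated correlation). FAD-binding berberine proteins rose for 11 of 16 and fell for 1 (camera adjusted p = 4.4e-05; adjusted p = 0.952 with an estimated correlation), and TIR-NBS-LRR disease resistance proteins rose for 26 of 45 and fell for 2 (camera adjusted p = 0.00791; adjusted p = 0.976 with an estimated correlation). NPH3 family proteins, named for a phototropism component, fell for 20 of 27 and rose for 1 (camera adjusted p = 1.2e-04; adjusted p = 0.952 with an estimated correlation). Pectin lyase-like proteins fell for 25 of 41 and rose for 4, SAUR-like proteins fell for 27 of 43 and rose for 8, and mitochondrial transcription termination factors fell for 17 of 30 and rose for 1 (camera adjusted p = 0.00123, 0.0234 and 0.0234; adjusted p = 0.976 for each with an estimated correlation). These 8 families were picked from the 17 after their values were seen. Their medians kept their sign under all 4 scalings, but those of 2 other called families, Integrase-type DNA-binding and RING/U-box proteins, changed sign (-0.08 to 0.22 and -0.00 to 0.32), so no direction is given for them.

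Groupings of the 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05. The real grouping called 11247 genes, the highest other 0, and 1 of the 10 splits, the real one, called as many. Every other split puts libraries of both groups together, so the difference between them widens the spread within its groups. Few calls were thus fixed in advance, and the 0 does not measure calls made by chance.

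Photorespiration, Calvin-Benson cycle and antenna transcripts lay lower in high light, with a median of -1.12 over 66 genes. Dilution of abundant transcripts by a few strongly risen ones would lower other genes of like abundance as far, but the median minus the lowest median was -0.35, taken over 10000 lists matched on mean expression, whose medians ranged centrally (95%) from -0.60 to 0.02. After taking out the trend on exon GC content and length the median was -1.12, and over the 58 members without a near-identical copy it was -1.09. These values argue against each of the 3 as the whole cause. A response to the change of light, CO2 and humidity stays open as a hypothesis, untested because these changed together with chamber and time.

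Clock genes moved as a later time of day would have it in 16 of 18 called members. The exceptions, RVE1 (0.64 ± 0.23) and RVE2 (2.71 ± 0.38), named after their values were seen, rose against it. In 13 refits, run after these results were seen, 15 to 19 of 16 to 20 called members followed, and RVE1 was called in 7 (edgeR adjusted p from 0.0122 to 0.187) and RVE2 in all 13. The 4 scalings, under which the median of the midday to evening list was at least 3.07, move all genes alike and so decide nothing about this pattern. A later sampling time may account for the 16 members and cannot be told apart from an effect of the treatment, because the groups differ by 3 h of treatment and the hours of sampling were not given in the sources used here.

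High CO2 replicate 2 was highest of the high CO2 libraries in 37 of 48 called genes with a fitted log2 fold change of at least 8 and at least 1000 mean counts in high light, and in 48 of the 69 with any count in high CO2 among all 97 at that fold change (11 of 21 outside the 48). Greater depth is argued against, as the median ratio of CPM to the mean of replicates 1 and 3 was 2.39 over those 69 genes; over all 97, of which 28 had 0 counts, the median log2 differences after adding 0.1 CPM were 0.26 and 0.31 to replicates 1 and 3, and 0.30 and 0.02 for log2 fold changes of 4 to 6. Carry-over of high light RNA or reads would give 1 ratio to some high light library. The best of 4 possible sources left a chi-square per degree of freedom of 3.45, above counting error alone but below the limit of 5 set for excluding a single source, with a fitted share of 0.194%. A trace of high light material may therefore be present and stays open, and a mild response in some plants of that pool was not tested.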
